A study of Mus musculus with 6 samples.

How the data were processed

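Small RNA sequencing of round spermatids, the haploid germ cells that follow meiosis, was analysed from 6 libraries of C57BL/6 mice at postnatal day 21. Of these, 3 libraries came from Miwi knockout (KO) males and 3 from wild-type (WT) males. MIWI (PIWIL1) and MILI (PIWIL2) are the PIWI proteins that bind pachytene piRNAs in the adult testis. Per the labels' protocols, small RNA was isolated with a mirVana kit and libraries were made with an Ion Total RNA-Seq kit. The labels number the libraries 1 to 3 in each genotype and do not say that each number is a separate animal. P-values of tests between libraries therefore measure only the spread between these samples, which may be technical.

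The authors deposited 2 tables of raw counts, in whole reads per reference sequence and library. Per the file headers, both were made with featureCounts v1.5.0-p2, with 1 feature for each reference sequence. Per the submitters' processing notes, cutadapt, DESeq2 and the mouse build mm9 were also used. The aligner and its settings, and the treatment of reads that match several sequences, are not given in the sources used here. The small RNA table holds 45932 entries, of which 39972 are named as piRNAs in the deposited names. The piRNA table holds 9924085 entries named by position in 773 clusters, and 2217610 of them had at least 1 count in any library. Each entry's name gives 1 position, strand and cluster. The indexed lengths hold 20 nt more than the RNA, as 249 of 249 tRNA entries show against the length in their names, and 20 nt were subtracted. In the piRNA table, 4552507 entries repeat the position, strand and length of an earlier entry. At the 955 such places with at least 2 entries of at least 200 counts, the highest entry had a median of 2.04 times the counts of the lowest, so the split of counts among these entries is uncertain.

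Reads of some miRNA genes appear to be counted in both tables, although single reads were not compared. Among 9 miRNA genes with at least 1000 counts in each table, 6 had counts within 1.2 times of each other, and the Mir19b-1 gene had 65463 counts in the piRNA table against 66971 for the mature miRNA. These matches were found at the gene positions of build GRCm38, although the notes name mm9. Coordinates are therefore given as in the deposited names, 1-based, and annotated with GRCm38 genes. Counts at annotated miRNA genes made up 1.17% of the piRNA table. The entry length was used in place of the read length, which the tables do not hold.

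Differential abundance was tested in each table separately with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15). P-values were adjusted with the Benjamini-Hochberg method, and an adjusted p of 0.05 was the threshold. All tests were two-sided. The design compared KO with WT without a block. The piRNA table was tested per entry and as sums in windows of 100 kb. Fixed lists of RNAs were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it, in limma 3.58.1, for lists with at least 3 tested members. The share of 29-32 nt among 25-32 nt counts and the shares of RNA classes were compared with exact permutation tests, whose smallest p for 3 against 3 is 0.1. Python 3.11.15 and scipy 1.17.1 were used for these. Some tests set RNAs or clusters against one another: camera at the preset correlation, the permutation tests of clusters and Fisher's exact test. Their p-values do not measure the spread between samples. Lengths of 25-28 nt and 29-32 nt were taken as those usual for MILI and for MIWI.

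The tests, the lists, the rule for named RNAs and a set of alternatives were chosen before the data were examined. The rule took up to 12 rises and 12 falls of the small RNA table without overlap between the genotypes, the 6 miRNAs with the highest mean CPM (counts scaled to the library total times its TMM factor), up to 4 members of each list by CPM, 4 rises, 4 falls and the 3 highest entries of the piRNA table, and the 8 highest windows with 4 rises and 4 falls among windows with a mean CPM of at least 50. The alternatives chosen then were DESeq2 1.42.0 size factors and its Wald test, other filters, library size without TMM factors, the replicate block, leaving out each library, other window sizes, other length limits and, for the piRNA table, TMM factors of the miRNAs. Alternatives chosen after seeing the data were TMM factors of the miRNAs within the small RNA table (with those of the piRNA table called miRNA scaling), TMM factors of all RNAs other than piRNAs, both replicate 3 libraries left out, entries of 1 place summed, clusters as units, windows of 1 length class, miRNAs alone as the comparison for lists, and fry under miRNA scaling. Members of RNA classes chosen for their change within the class, the single clusters and the tRNA genes were also chosen after their values were seen.

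Table totals ranged from 747443 to 5037232 counts for small RNAs and from 1009902 to 6623310 for piRNAs, with lower totals in the KO libraries. A count of 3 corresponded to between 0.596 and 4.01 CPM of the table total, without TMM factors, in the small RNA table. Folds against a genotype with 0 counts are lower bounds against 3 counts over the group, with TMM factors unless library size alone is named, and intervals and floors cover counting error only. No pair of libraries of 1 genotype was alike within sampling noise, with a chi-square per degree of freedom between 1.40 and 15.5. Every sample column was used.

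The fits were tested on simulated data at a dispersion of 0.02, with 100 features changed at each fold. In the small RNA table, with 24269 features tested, 54 of the 100 changed 2-fold and 90 of the 100 changed 4-fold were called, with 4 false calls. In windows, with 740 tested, 87 and 99 were called, with 13 false calls. In piRNA entries, with 45243 tested, 12 and 64 were called, with 4 false calls. Camera called a simulated raised list of 20 RNAs. Of 100 random lists, 3 passed 0.05. The simulated RNAs were drawn independently of one another. The simulation therefore does not show how often camera at the preset correlation calls lists whose RNAs vary together.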

Results

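Small RNAs of purified round spermatids were counted in 3 Miwi KO and 3 WT libraries. The small RNA table held 1293676, 747443 and 1335013 counts in KO replicates 1 to 3 and 3114845, 3287255 and 5037232 in WT replicates 1 to 3. The piRNA table held 1772234, 1009902 and 1785660 counts in KO and 4059156, 4359620 and 6623310 in WT. The targeted mRNA, Miwi (Piwil1), was not analysed here because the tables count small RNAs, so the genotype labels were not checked on it. The comparison addressed whether the piRNA profile of round spermatids differs without MIWI.

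Cluster piRNAs were shorter in Miwi KO round spermatids. Entries of 29-32 nt, the length usual for MIWI, made up 22.1% ± 1.11 (SD, n = 3) of the 25-32 nt counts in KO and 80.7% ± 0.581 (SD, n = 3) in WT, a difference of -58.6 percentage points. The most frequent length was 27 nt in each KO library and 30 nt in each WT library. RNAs of 30 nt made up 5.76% ± 0.352 of the piRNA table counts in KO and 28.5% ± 0.0472 in WT, and RNAs of 27 nt made up 22.4% ± 0.0920 in KO and 5.16% ± 0.161 in WT (SD, n = 3). The genotypes did not overlap, and the exact permutation test gave p = 0.1, the smallest that 3 against 3 samples allow. Among single entries tested with edgeR, 28243 of 31488 entries of 29-32 nt fell and 1456 rose, while 11551 of 22626 entries of 25-28 nt rose and 2714 fell. Camera placed the 29-32 nt entries below the 25-28 nt entries with p = 6.17e-141, and p = 0.00258 with an estimated correlation. In the annotated piRNAs of the small RNA table the 29-32 nt share differed less, at 71.4% ± 0.280 in KO and 85.7% ± 0.167 in WT (SD, n = 3).

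**Figure D1:**
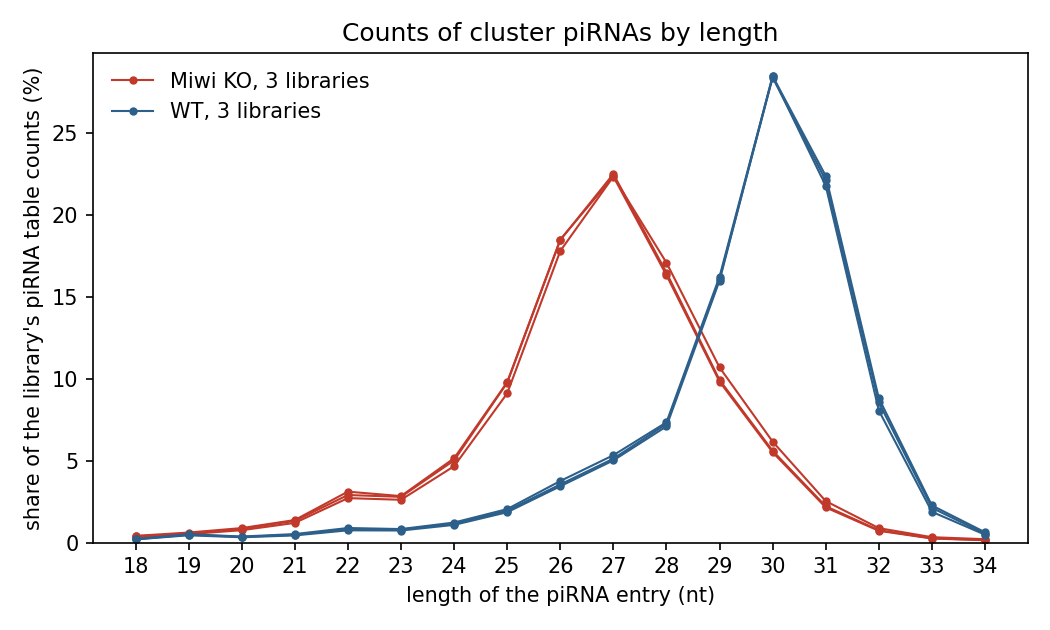
Share of the piRNA table counts (percent, vertical axis) at each entry length (nt, horizontal axis), with 1 line for each of the 3 Miwi KO and 3 WT libraries. The KO lines peak at 27 nt and the WT lines at 30 nt.

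Relative to miRNAs, long piRNAs were scarce in KO and short piRNAs were not. Cluster piRNA counts were 726 ± 33.4 per 100 miRNA counts in KO and 2391 ± 261 in WT (SD, n = 3), 3.30-fold lower in KO. The 29-32 nt class was 13.0-fold lower, at 138 ± 11.6 against 1799 ± 209 (SD, n = 3). The 25-28 nt class was at 485 ± 22.9 in KO and 428 ± 35.8 in WT, with overlapping libraries (exact permutation p = 0.2, n = 3), and the 18-24 nt class was at 99.1 ± 5.19 and 101.5 ± 5.29. tRNA counts, between 1.23 and 2.03 in the KO libraries and between 6.04 and 10.1 in the WT libraries, were 4.99-fold lower in KO. Endo-siRNAs, small RNAs from double-stranded precursors, were at 2.47 ± 0.151 and 2.93 ± 0.309. The classes without overlap had exact permutation p = 0.1. As a share of both tables, miRNAs were 7.93% ± 0.357 of KO counts and 2.39% ± 0.247 of WT counts, and cluster piRNAs were 57.5% ± 0.293 and 56.8% ± 0.215 (SD, n = 3, exact permutation p = 0.1 and adjusted p = 0.167 for each over 10 classes). On this scale tRNAs were 0.119% ± 0.0349 of KO counts and 0.175% ± 0.0329 of WT counts, with overlapping libraries (SD, n = 3, exact permutation p = 0.2). Without the 10 features with the highest mean share of the table totals, the miRNA difference of 5.54 points became 2.57 points and the cluster piRNA difference of 0.699 points became 2.47 points. Within the small RNA table alone the miRNA difference was 13.1 points. Annotated piRNAs of the small RNA table were 34.1% ± 0.245 of KO counts and 40.4% ± 0.268 of WT counts (SD, n = 3). Per 100 miRNA counts they were at 430 ± 21.5 in KO and 1702 ± 193 in WT (SD, n = 3), 3.96-fold lower in KO. Reads that appear to be counted in both tables enter the shares of both tables in each. Such reads were examined only at miRNA genes, so how far piRNA reads are counted in both is not known.

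**Figure D2:**
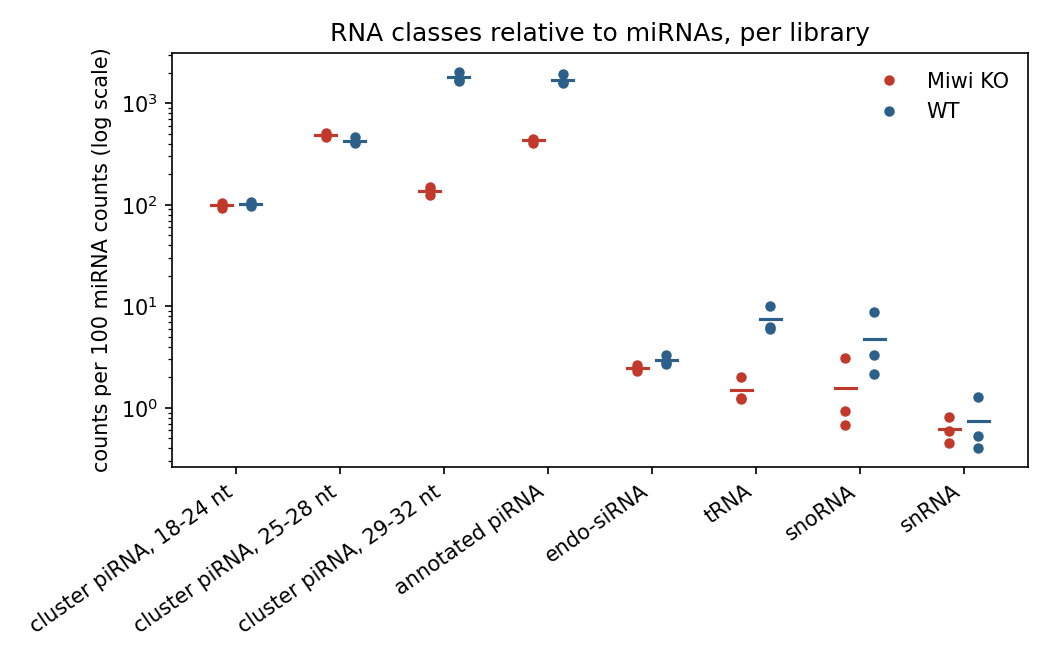
Counts of each RNA class per 100 miRNA counts (vertical axis, log scale) in single libraries (points), with the mean of the 3 libraries of a genotype (bars). Cluster piRNAs of 29-32 nt were 13.0-fold and tRNAs 4.99-fold lower in Miwi KO, while cluster piRNAs of 25-28 nt overlapped between genotypes.

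Among annotated small RNAs, nearly every miRNA and most endo-siRNAs rose against the table as a whole in KO, and more piRNAs fell than rose. With TMM factors of the whole table, 338 of 348 miRNAs rose and 2 fell, 97 of 120 endo-siRNAs rose and 11 fell, and 8128 of 24054 piRNAs rose and 10174 fell. Under miRNA scaling, which moved the median log2 change of the table by -1.81, 40 miRNAs rose and 30 fell, 49 endo-siRNAs rose and 29 fell, and 1737 piRNAs rose and 18256 fell. In all, edgeR called 18812 of 24682 RNAs, 8613 up and 10199 down. The split was 1827 up and 18430 down under miRNA scaling, and 2448 up and 17896 down under scaling on RNAs other than piRNAs, which moved the median by -1.63. The genotypes did not overlap in 77.3% of the RNAs, where chance gives 10%.

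Single RNAs changed far more than their classes. The piRNA with the largest rise, piRNA 21504-1 (29 nt), had 713 counts in KO and 15 in WT, a log2 change of 7.46 ± 0.26 (SE, edgeR adjusted p = 3.46e-26), and piRNA 2361-3 (26 nt) had 4929 and 273 counts, a change of 6.07 ± 0.21 (edgeR adjusted p = 1.97e-26). piRNA 3970-2 and piRNA 274-509 rose by 6.72 and 6.32. Under miRNA scaling piRNA 21504-1, piRNA 2361-3, piRNA 3970-2 and piRNA 274-509 rose by 5.65, 4.26, 4.90 and 4.51. Of the 12 largest rises, 3 were endo-siRNAs of 22 or 23 nt, with log2 changes of 6.39 for endo-siRNA-Sp371, 6.27 for endo-siRNA-Sp244 and 6.21 for endo-siRNA-Sp190, and under miRNA scaling they stayed at 4.60, 4.47 and 4.39. The 12 largest falls were all piRNAs of 30-32 nt with 0 counts in KO. piRNA 24313-1 had 3374 counts in WT and was at least 293-fold lower in KO, piRNA 16426-1 had 3075 and was at least 267-fold lower, and piRNA 20377-1 had 1642 and was at least 142-fold lower.

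The most abundant miRNAs were members of the family of miR-34 and miR-449, which is abundant in meiotic and postmeiotic germ cells, and of the miR-17-92 and miR-15/16 families. With TMM-adjusted library sizes, miR-34b-5p was at 41543 ± 5123 CPM in KO and 10277 ± 1479 CPM in WT (SD, n = 3), a log2 change of 2.02 ± 0.20 (SE, edgeR adjusted p = 2.61e-12), and of 0.22 under miRNA scaling (edgeR adjusted p = 0.296). The log2 changes of miR-34c-5p, miR-15b-5p and miR-18a-5p were 2.20, 2.25 and 2.24, and 0.40, 0.43 and 0.46 under miRNA scaling, where each still passed. Those of miR-16-5p and miR-19b-3p were 1.85 and 1.96, and 0.05 and 0.15 under miRNA scaling, where neither passed. Chosen after their values were seen, miR-184-3p rose by 3.83 and 2.01 under the respective scalings, and miR-468-5p changed by -1.67 and -3.47, with 2938 counts in KO and 34360 in WT.

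Most members of the 17 miRNA lists rose against the table. With TMM factors of the whole table all tested members rose in 15 of these lists, the exceptions being miR-451a in the erythroid list and 1 of 11 members of the Dlk1-Dio3 cluster, and the counts adjusted over the list alone were the same. Camera called 14 of 19 lists at the preset correlation and 0 of 19 with an estimated correlation, where the lowest adjusted p was 0.127. Under miRNA scaling camera, which sets a list against the other RNAs of the table, placed 18 of 19 lists up, among them lists whose members fell.

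Germ cell miRNAs rose against the table together with the other miRNAs. All 11 tested members of the list of miR-34 and miR-449 rose (camera adjusted p = 1.36e-05, adjusted p = 0.189 with an estimated correlation). Under miRNA scaling 5 rose, 3 fell and 3 did not pass, and adjusted over the list alone the counts were the same. Among those that rose were miR-449a-5p at 0.56 and miR-34b-3p at 0.67. Those that fell were miR-34a-3p at -0.93, miR-449b at -0.58 and miR-34a-5p at -0.43. This list did not pass with fry under miRNA scaling (adjusted p = 0.254) or with camera among miRNAs alone (adjusted p = 0.514). All 21 tested miRNAs of the late germ cell list rose (camera adjusted p = 1.01e-10, adjusted p = 0.127 with an estimated correlation), and under miRNA scaling 8 rose and 0 fell, or 6 and 0 adjusted over the list alone. This list shares 10 of its tested members with other lists. All 31 members of the X-linked germ cell clusters rose (camera adjusted p = 2.34e-10, adjusted p = 0.189 with an estimated correlation), while under miRNA scaling 0 rose and 4 fell, or 0 and 0 adjusted over the list alone, and the median was -0.10. All 13 tested let-7 miRNAs, which accumulate in differentiated cells, rose (camera adjusted p = 3.41e-07, adjusted p = 0.189 with an estimated correlation). Under miRNA scaling 6 rose and 0 fell, or 5 and 0 adjusted over the list alone, with let-7a-5p at 0.98 and let-7f-5p at 0.73. With miRNAs alone as the comparison, camera placed the let-7 and the late germ cell lists above other miRNAs (adjusted p = 0.00278 for each), with adjusted p = 0.576 and adjusted p = 0.424 with an estimated correlation. It placed the X-linked clusters below other miRNAs with adjusted p = 0.0970, which did not pass. The miR-17-92 list (16 members, camera adjusted p = 3.09e-07), the C2MC list from the Sfmbt2 gene (37 members, adjusted p = 2.34e-10) and the spermatogonial list (10 members, adjusted p = 0.000924) rose in full. Their adjusted p with an estimated correlation was 0.189, 0.219 and 0.189. Under miRNA scaling 1 member of the miR-17-92 list and 2 members of the C2MC list rose, 1 member of the spermatogonial list fell, and 0 of these passed adjusted over the list alone.

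Markers of other testis cells rose against the table, and few rose relative to miRNAs. All 18 mesenchymal and peritubular miRNAs rose (camera adjusted p = 5.47e-06, adjusted p = 0.189 with an estimated correlation), while under miRNA scaling 0 rose and 5 fell, or 0 and 4 adjusted over the list alone, and the log2 change of miR-143-3p, a smooth muscle miRNA, was 1.33 and then -0.48. With miRNAs alone as the comparison, camera placed this list below other miRNAs with adjusted p = 0.0970, which did not pass. The Sertoli and gonadal list (5 of 5 up, camera adjusted p = 0.00347), the endothelial list (4 of 4 up, adjusted p = 0.00503), the erythroid list (4 of 5 up, adjusted p = 0.0124) and the leukocyte list (10 of 10 up, adjusted p = 3.72e-05) each had adjusted p = 0.189 with an estimated correlation. Under miRNA scaling 0, 0, 0 and 2 of their members rose and 0, 0, 1 and 1 fell, and adjusted over the list alone 0, 0, 0 and 1 rose and 0, 0, 1 and 1 fell. The log2 changes of miR-126a-3p (endothelial) were 1.85 and 0.05 under the respective scalings, and those of miR-451a (erythroid) were 0.67, which did not pass, and -1.13. All 8 tested miRNAs of the off-tissue list, known mainly from brain, muscle and islets, rose (camera adjusted p = 0.000153, adjusted p = 0.189 with an estimated correlation), and 4 still rose under miRNA scaling, or 3 adjusted over the list alone, with miR-375-3p at 0.93 and miR-124-3p at 0.79.

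Of the remaining lists, the Dlk1-Dio3 cluster had 10 of 11 members up (camera adjusted p = 0.0286, adjusted p = 0.189 with an estimated correlation), and 1 under miRNA scaling, or 0 adjusted over the list alone. The camera call was lost without WT replicate 2 (adjusted p = 0.0529) or without WT replicate 3 (adjusted p = 0.0672). The miR-290 and miR-302 list (3 members), the miR-183 cluster (3) and the miR-200 family (5) had all tested members up, with camera adjusted p = 0.133, 0.244 and 0.0898, which did not pass. All 3 passed with fry (adjusted p = 0.000181, 0.00503 and 0.000296). The miR-290 and miR-302 list and the miR-200 family also passed with camera under miRNA scaling, against all other RNAs (adjusted p = 0.0307 and 0.0245). Under miRNA scaling 1, 0 and 0 members of the 3 lists rose and 0 fell, and fry did not pass (adjusted p = 0.0767, 0.104 and 0.990). With miRNAs alone as the comparison, camera did not pass (adjusted p = 0.528, 0.506 and 0.952). Among 37 C/D box snoRNAs, guides of RNA methylation, 3 rose and 0 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.661), while under miRNA scaling 34 fell and 34 fell adjusted over the list alone. Against the other RNAs, camera placed this list up under miRNA scaling (adjusted p = 0.0249), opposite to its members' own changes. The replicate 3 libraries of both genotypes were rich in snoRNAs, at 0.241% of both tables in KO against 0.0718% and 0.0564% in the other KO libraries, and at 0.186% in WT against 0.0825% and 0.0558%. Of 13 mitochondrial RNAs 5 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.191), and under miRNA scaling 0 rose and 5 fell. Camera placed this list up without KO replicate 1 (adjusted p = 0.0171), without KO replicate 2 (adjusted p = 0.0485) and under miRNA scaling (adjusted p = 0.0245). The replicate 3 libraries were also rich in mt-tRNAs, at 0.0335% of both tables in KO against 0.00802% and 0.00825%, and at 0.0219% in WT against 0.00758% and 0.00824%. Scarna9 was the tested member of the scaRNA list, at 0.82, which did not pass (edgeR adjusted p = 0.054). It passed with a stricter filter (edgeR adjusted p = 0.0298) and without KO replicate 1 (0.0444), KO replicate 2 (0.0273), WT replicate 3 (0.000686) or both replicate 3 libraries (0.0357). The H/ACA list had 0 tested members, and the Y RNA and 7S RNA list 0.

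Counts of 9 of 13 tRNA isotypes were lower in KO without overlap of the libraries, by folds of unequal size. Relative to miRNA counts, tRNA-Asp was 21.8-fold, tRNA-Glu 19.1-fold and tRNA-Gly 6.17-fold lower in KO, tRNA-Cys, tRNA-Ala and tRNA-His between 2.78-fold and 2.80-fold lower, tRNA-Val 2.55-fold lower, tRNA-Lys 2.20-fold lower and tRNA-Ser 1.64-fold lower. tRNA-Met, at 0.435 ± 0.144 counts per 100 miRNA counts in KO and 0.475 ± 0.0796 in WT, and tRNA-Gln, at 0.0762 ± 0.0385 and 0.0845 ± 0.0296 (SD, n = 3), overlapped. For 13 isotypes the exact permutation p was at least 0.1 and the adjusted p at least 0.144. With whole-table TMM factors, 23 of 53 tRNA entries rose and 11 fell, and under miRNA scaling 0 rose and 33 fell. The entry of tRNA-Asp-GTC chr10.trna866, chosen after its values were seen, had 90 counts in KO and 3309 in WT, a log2 change of -3.21, and of -5.04 under miRNA scaling. Entries of 1 isotype share sequence, so the split of counts among them is uncertain.

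At the 8 windows with the most counts 29-32 nt piRNAs fell under miRNA scaling, while 25-28 nt piRNAs rose at 4 and did not pass at 4. In the window at 18:67000001-67100000 (near Gnal), the log2 change was -1.86 ± 0.04 (SE, edgeR adjusted p = 9.04e-20), and under miRNA scaling it was -4.42 for 29-32 nt and -0.18 for 25-28 nt, the latter not past the threshold. The windows at 2:92500001-92600000 (Gm13817, Chst1), 15:59200001-59300000 (Gm36617), 6:127800001-127900000 (Gm40402) and 5:149800001-149900000 (Gm21221) changed by -1.18, -1.34, -1.26 and -1.54. Under miRNA scaling their 29-32 nt counts changed by -3.82, -3.88, -3.78 and -4.14, and their 25-28 nt counts by 0.21, 0.11, 0.35 and -0.08, of which 0.35 passed. The windows at 5:113300001-113400000 (1700016C19Rik) and 7:73800001-73900000 (Gm10619) changed by -0.91 each, -1.53 each under miRNA scaling and 0.07 each with library size alone. Under miRNA scaling their 25-28 nt counts rose by 0.43 and 0.32, and their 29-32 nt counts changed by -3.42 and -3.28. The window with the most counts, 17:27300001-27400000 (Gm10505, Mir7214), changed by 0.34 with TMM factors and by -0.28 under miRNA scaling, with 0.93 for 25-28 nt and -2.21 for 29-32 nt.

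Both lengths rose at 3 of the 4 windows with the largest rises and fell at 3 of the 4 with the largest falls. The largest rises were at 15:73300001-73400000 (Ptk2, 1.96), 11:6100001-6200000 (Nudcd3, 1.91), 5:124100001-124200000 (Ogfod2, 1.84) and 16:53500001-53600000 (no annotated gene, 1.74), and under miRNA scaling they were 1.33, 1.29, 1.21 and 1.11. Their 25-28 nt counts changed by 2.40, 1.80, 1.97 and 2.38 under miRNA scaling, and their 29-32 nt counts by 0.60, 0.89, 0.74 and -0.84, each past the threshold. The largest fall was at 5:101800001-101900000 (Wdfy3, Gm20548), with 171 counts in KO and 25316 in WT, a log2 change of -6.49 ± 0.09 (SE, edgeR adjusted p = 3.10e-22), and under miRNA scaling of -4.27 for 25-28 nt and -7.95 for 29-32 nt. Falls at 17:79300001-79400000 (Cdc42ep3, -4.89), 3:97100001-97200000 (Acp6 and the tRNA-Glu gene n-TEctc12, -3.87) and 14:65100001-65200000 (Fzd3, -3.80) followed. Under miRNA scaling their 25-28 nt counts changed by -3.97, -3.50 and -0.10, the last not past the threshold, and their 29-32 nt counts by -6.47, -5.50 and -6.78. The fall at 3:97100001-97200000 was mostly at a tRNA gene. Of the 22105 WT counts in this window, n-TEctc12 held 18628 of 29-32 nt and 1520 of 25-28 nt. In all, edgeR called 429 of 749 windows, 196 up and 233 down. The genotypes did not overlap in 61.9%, where chance gives 10% for a single window, and windows do not vary independently. The split was 26 up and 437 down under miRNA scaling, which moved the median by -0.62, and 568 up and 108 down with library size alone, which moved it by 0.98. With 29-32 nt entries alone under miRNA scaling, 4 windows rose and 423 fell of 501, and with 25-28 nt entries 81 rose and 165 fell of 724.

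Single clusters showed the same shift of length. Of 269 clusters with at least 1000 counts, chosen after the data were seen, 263 had a lower 29-32 nt share in KO, 241 of them without overlap of the libraries, and 6 a higher one, 1 without overlap. The median share was 22.8% in KO and 65.4% in WT. Among the 25 largest clusters the share lay between 17.8% and 28.5% in KO and between 66.8% and 88.1% in WT.

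**Figure D3:**
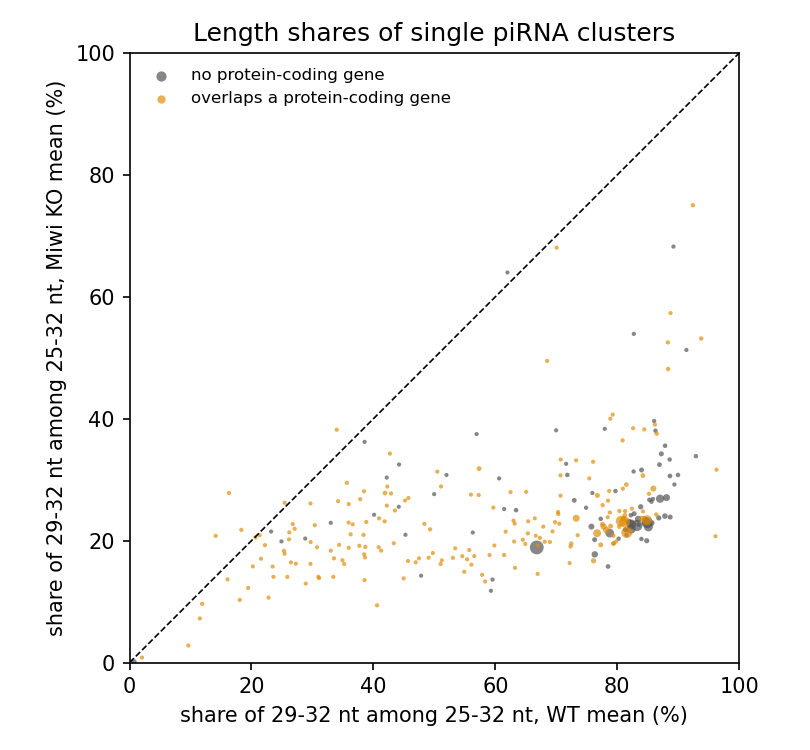
Share of 29-32 nt among 25-32 nt counts in 269 piRNA clusters, as the mean of 3 WT libraries (horizontal axis, percent) and of 3 Miwi KO libraries (vertical axis, percent), with point area growing with the counts, colour for overlap with a protein-coding gene and a dashed line of equal shares. The share was lower in KO in 263 clusters, and its median was 22.8% in KO and 65.4% in WT.

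Some single piRNA entries with 0 counts in 1 genotype were abundant in the other, in both directions. Counts are split among entries of the same place, so 0 counts at 1 entry need not mean that the RNA was absent. The entries named here were not summed with others of their place. The largest falls were entries of 30 or 31 nt in no annotated transcript with 0 counts in KO. The entry at 2:151152043-151152072 had 5399 counts in WT and was at least 547-fold lower in KO by library size alone (2137-fold with TMM factors), and those at 14:24103481-24103511, 12:98416194-98416224 and 15:59272242-59272271 had 4961, 4677 and 4447 counts in WT and were at least 502-fold, 473-fold and 450.1-fold lower by library size alone (1963-fold, 1851-fold and 1760-fold with TMM factors). The largest rises were shorter. The 28 nt entry at 17:66177592-66177619, in no annotated transcript, had 1009 counts in KO and 0 in WT, at least 283-fold higher, and the 27 nt entry at 11:6142569-6142595, opposite to an intron of Nudcd3, had 507 and 0, at least 142-fold higher. At 11:103433145, entries of 25 and 26 nt with a shared left end were at least 113-fold and 105-fold higher in KO. Of the 3 highest entries, 2 shared the place 18:67044736-67044765 (30 nt), with 7 and 12 counts in KO and 13431 and 13315 in WT, and 1 lay in the UTR of Ubxn7 (16:32390318-32390339, 22 nt), with 37381 counts in KO and 30593 in WT, a log2 change of 0.02 ± 0.20 (SE, edgeR adjusted p = 0.913), which did not pass. The change of this entry was -0.39, -0.30 and -0.35 without WT replicates 1, 2 and 3, and passed without replicate 2 or 3. It was 2.01 with library size alone and 0.93 with a stricter filter, and passed in both.

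In all, edgeR called 46092 of 57318 piRNA entries, 14145 up and 31947 down. The genotypes did not overlap in 79.8%, where chance gives 10% for a single entry, and entries do not vary independently. The split was 26637 up and 28036 down with library size alone, which moved the median by 1.92, and miRNA scaling moved the median by 0.35. The count was 71304, 74366 and 71610 without KO replicates 1, 2 and 3, of 95468, 98429 and 96581 entries tested. It was 27694, 28409 and 28415 without WT replicates 1, 2 and 3, of 44289, 44533 and 44757 tested. The number of entries that passed the filter thus changed along with the count.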

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

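Chosen after seeing the data were miRNA scaling within the small RNA table, scaling on RNAs other than piRNAs (non-piRNA scaling), both replicate 3 libraries left out, entries of 1 place summed, clusters as units, windows of 1 length class, miRNAs alone as the comparison for lists, and fry under miRNA scaling. The shift in length kept its direction in all alternatives run, at -59.3 to -58.3 points when 1 library was left out and -60.8 points for 29-33 against 24-27 nt. Called RNAs of the small RNA table numbered between 16778 and 22386 over the alternatives. Called windows were 676 with library size alone and 246 with 25-28 nt entries alone under miRNA scaling. Called piRNA entries were between 27694 and 74366 when 1 library was left out, with between 44289 and 98429 entries tested, and 213784 without a filter, with 2217610 tested. The lists past the threshold, of 19, were 0 with an estimated correlation, 5 with fry under miRNA scaling, 17 with fry and 18 with camera under miRNA scaling. The miRNA share difference was 13.1 points within the small RNA table alone, and without the 10 highest features it was 2.57 points, and 2.47 points for cluster piRNAs. Except where a changed number of tested entries is named, the cause was not tested.

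The log2 change of the following RNAs was above 0 with whole-table factors, where Snord4a, Snord58b, Snord37, miR-451a, mt-Tv and Scarna9 did not pass and the others did. Of these others, miR-34a-3p lost its call with DESeq2 size factors (adjusted p = 0.0567), its Wald test (0.151), no filter (0.156), library size alone (0.108), both replicate 3 libraries left out (0.307) and each KO replicate left out (0.0788 to 0.172). miR-324-3p and miR-96-5p lost theirs with the Wald test (0.0537 and 0.0568), no filter (0.0600 and 0.0583), both replicate 3 libraries left out (0.179 and 0.204), and without KO replicate 3 (0.0855 and 0.110) or WT replicate 3 (0.0891 and 0.0922), and miR-324-3p also without KO replicate 1 (0.0586). Snord98 lost its call with the Wald test (adjusted p = 0.410), library size alone (0.0673) and both replicate 3 libraries left out (0.294). It also lost it without KO replicate 3 (0.0905), WT replicate 1 (0.143) or WT replicate 2 (0.155). The log2 change was below 0 under miRNA scaling for miR-743b-3p (-0.015), miR-465a-3p (-0.10), miR-183-5p (-0.093), miR-669a-3p (-0.059), miR-30d-5p (-0.022), miR-202-5p (-0.031), miR-140-5p (-0.14), miR-9-3p (-0.0039) and Scarna9 (-1.01). Under miRNA scaling and non-piRNA scaling, in this order, it was -0.48 and -0.29 for miR-182-5p, -0.75 and -0.57 for miR-96-5p, -0.46 and -0.27 for miR-200a-3p, -0.44 and -0.25 for miR-379-5p, -0.20 and -0.019 for miR-136-5p, -0.35 and -0.16 for miR-145a-5p, -0.48 and -0.30 for miR-143-3p, -0.37 and -0.19 for miR-140-3p, -0.31 and -0.13 for miR-503-5p, -1.13 and -0.95 for miR-451a, -0.51 and -0.33 for miR-342-3p, -0.24 and -0.061 for miR-31-5p, -0.96 and -0.78 for miR-324-3p, -0.93 and -0.74 for miR-34a-3p, -0.48 and -0.29 for mt-Rnr2, -0.28 and -0.10 for mt-Tm, -0.55 and -0.36 for Gm23262, -0.59 and -0.40 for Gm25835, -0.91 and -0.73 for Snord98, -1.73 and -1.54 for Snord4a, -1.73 and -1.54 for Snord58b, -1.44 and -1.25 for Snord37, and -1.13 and -0.95 for mt-Tv. The window 17:27300001-27400000 was at -0.28 under miRNA scaling, and those at 5:113300001-113400000 and 7:73800001-73900000 were at 0.071 each with library size alone. With fry under miRNA scaling, lists that camera placed up had the direction down, past the threshold for the X-linked clusters (adjusted p = 0.00581) and Dlk1-Dio3 (0.0235) and not past it for the others, with 0.0553 for mesenchymal, 0.112 for Sertoli, 0.990 for erythroid and 0.372 for spermatogonial miRNAs.

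When 1 library was left out, the change ranged from -0.53 to 1.61 for Snord98, -1.21 to 0.75 for Snord4a, -1.16 to 0.90 for Snord58b, -0.92 to 1.10 for Snord37 and -0.89 to 1.24 for mt-Tv, each lowest without KO replicate 3. Without both replicate 3 libraries Snord4a was at -0.48. The class share difference ranged from -0.0044 to 0.0087 points for mt-tRNAs and from -0.044 to 0.054 points for snoRNAs, each lowest without KO replicate 3, and the snoRNA difference was -0.011 points without WT replicate 2. The Ubxn7 entry ranged from -0.39 to 0.17 and was below 0 without WT replicate 1, 2 or 3. Of 129 named small RNAs, 16 named windows, 11 named piRNA entries and 19 lists, the others were the same in most settings, and under miRNA scaling 103 of 175 were the same, 33 weaker, 6 stronger and 33 reversed.

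Whether the replicate numbers pair the libraries stayed open. The correlations of same-numbered libraries were low, at 0.028, 0.095 and 0.137, but each library correlated best with its own number. The replicate 3 libraries of both genotypes were also rich in snoRNAs and mt-tRNAs. With the replicate as a block, 18914 small RNAs, 440 windows, 44569 piRNA entries and 15 lists were called. Calls were gained for the miR-200 family (adjusted p = 0.0419), Scarna9 (0.0189), mt-Tv (0.0142) and mt-Ts2 (0.0323), and miR-34a-3p (0.0553) no longer passed. For the 10 splits of 6 libraries into 3 and 3, too few for a share under 0.05, the real split gave 18812 small RNAs, 429 windows and 46092 piRNA entries, and the highest other gave 0 for each, so 1 split was as large. For lists the real split gave 14 and the highest other 18, with 7 splits as large. Alternatives with entries of 1 locus and with entries at their first locus, chosen before the data were examined, were not run, because each name gives 1 locus. Of 100 simulated 2-fold changes, 12 were called among piRNA entries, 54 among small RNAs and 87 among windows. The simulation used the dispersion of the small RNA table for all 3. It changed far fewer features than were called here, equally up and down. The power and false calls of the real fits may therefore differ. Depth itself was not varied.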

Other observations

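All tests below except Fisher's exact test of miRBase entries were chosen after the result was seen. Clusters that overlap a protein-coding gene changed less than others. Under miRNA scaling the median log2 change was -0.91 in 188 clusters overlapping a protein-coding gene and -1.51 in 81 others (permutation p = 0.00787, over clusters and not libraries). Their median WT share of 29-32 nt was 56.9% and 81.5%. Over all 269 clusters, a higher WT share went with a lower log2 change (Spearman rho = -0.823, permutation p = 1e-05, over clusters and not libraries). WT counts enter both of these values. Overlap with a gene and the WT share were not separated, so the difference may lie in the lengths. At 798 5′ ends with at least 1000 counts of 30-31 nt in WT, KO had 54851 counts of 30-31 nt against 1912316 in WT, and 130411 counts of 26-27 nt against 99641. These ends were picked for their WT count of 30-31 nt, which by itself favours a lower KO count. The values are raw counts summed over the libraries of a genotype, not scaled for the lower KO totals.

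The lower share of 29-32 nt piRNA counts in Miwi KO was weighed against selection by length in library making and against somatic cells in the KO samples. At 387 5′ ends holding both lengths, the change of the log2 ratio of 30-31 nt to 26-27 nt counts spanned 4.51 between its 10th and 90th percentile. Between WT libraries the span was at most 1.13. A selection that acts equally within each of these pairs of lengths needs 1 change at every end, and lengths within a pair were not matched. Somatic cells would need late germ cell miRNAs to fall against somatic miRNAs by about the change of 29-32 nt piRNAs, -3.70 per miRNA count. This holds only if the listed late germ cell miRNAs are scarce in somatic cells, which was not checked. The median of the 17 late germ cell miRNAs lay 0.430 above that of the 37 somatic ones. Somatic cells in place of round spermatids would also lower 25-28 nt cluster piRNAs. These were at 485 ± 22.9 per 100 miRNA counts in KO and 428 ± 35.8 in WT (SD, n = 3). The loss of the MIWI protein, which binds the longer piRNAs, may underlie the pattern, as a hypothesis found and examined on the same data. A different share of earlier germ cell stages in the KO samples was not tested and stays open.

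The lower tRNA counts per miRNA count were weighed against a change of the miRNA amount, the denominator, and against selection by length. The highest isotype fold, of tRNA-Asp, was 19.95 times the lowest, of tRNA-Met, and between 7.87 and 39.0 times over the 9 pairs of 1 WT and 1 KO library, where a changed denominator needs equal folds. At tRNA genes in clusters, the fold of 29-32 nt RNAs ranged from 49.6 at the tRNA-Glu gene n-TEctc12 (3:97158085-97158156, 371 counts in KO and 18628 in WT) to 1.72 at the tRNA-Pro gene n-TPagg6 (6:29388824-29388895, 103 and 174 counts, overlapping libraries), a ratio of 28.8. Over the pairs of libraries the folds lay between 34.5 and 67.9 at n-TEctc12 and between 0.547 and 3.30 at n-TPagg6. A selection that acts equally on all RNAs of 29-32 nt does not give this difference. Lengths inside the class were not matched between the genes, so a selection that differs inside it was not tested. For cluster piRNAs, the ratio of WT to KO shares rose from 1.59 at 29 nt to 10.8 at 32 nt. The genotype remains a possible explanation, as a hypothesis, and a difference in cell stage was not tested.

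Of 339 miRBase entries matched to a gene, 30 fell under miRNA scaling, and reads of piRNA precursors counted at miRBase entries were weighed as their source. Of these 30, 3 had a gene in a piRNA cluster (exact 95% interval of their share 2.11% to 26.5%). Precursors read at the miRNA gene itself in the 773 named clusters therefore do not account for the 27 others. Precursors from outside these clusters, and reads that match several sequences, were not checked. Entries with a gene in a cluster fell in 3 of 30 cases and others in 27 of 309 (Fisher's exact p = 0.739, two-sided), which does not show that the shares are equal. For miR-468-5p, miR-7210-3p and miR-7229-3p, the entries that fell with a gene in a cluster, reads of cluster precursors may still be the source. The genotype stays open for all 30, as untested.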
